A study of Lysinibacillus sp. B2A1 with 3 samples.

How the data were processed

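Total RNA was extracted with Trizol from log-phase cells that had been washed with buffered saline and held for 3 h without arsenic, with 5 mM arsenite or with 50 mM arsenate, per the labels' protocols. Libraries were built with a strand-specific kit (Agilent SureSelect) and sequenced on an Illumina system, per the labels' protocols. The submitters' processing notes name bcl2fastq and Trimmomatic 0.32. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here.

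The authors deposited 2 tables, each with 3 columns for the 3 libraries, and 0 columns of other samples were present. The first table holds a signal that the authors made, as its values show, by dividing read counts per gene by 1 size factor per library before it was deposited. Within 0.02 reads, or a relative 1e-05, 99.7% of the control values above 0, 99.7% of the arsenite values and 99.7% of the arsenate values were whole multiples of a single step. A read was worth 0.818, 1.28 and 0.953 in the deposited control, arsenite and arsenate columns, and the product of these steps was 0.9996. The values that were not whole, 16, 13 and 14 rows in control, arsenite and arsenate, all lie in loci that other rows share, and were rounded to whole reads. The second table gives FPKM as deposited by the authors, with a gene symbol or locus tag and a locus. The design had been fixed for raw counts. Since the files hold scaled counts, the reads were recovered by dividing by the step, and the planned ratios were computed on the recovered reads. No count test was run, since 1 library per group leaves no residual degrees of freedom.

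Of the 5417 rows 407 carry a symbol (346 different symbols) and the other 5010 a locus tag only. The files do not pair tags with product names, so gene lists were matched by symbol alone. Of the rows, 1317 have a locus that other rows share, 1071 of them among the tested rows. Among the genes named below, sat, cysC, sufD, msrB, hisA, ilvB, fliH, isdC, dltA and purE lie in such loci. So does the mdh row at 2055526 to 2057112. How reads were divided within these loci is not given in the sources used here. The 11 rrf rows (5S ribosomal RNA), with 236, 79 and 210 reads in control, arsenite and arsenate, were left out of scaling and counts. The libraries held 11022559 reads (control), 11081333 (arsenite) and 10892999 (arsenate). Rows at 0 numbered 270, 310 and 269. The 10 rows with most reads took 16.9%, 22.2% and 19.8% of the reads.

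Libraries were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, taken over the 3 libraries (1.235 for control, 0.774 for arsenite, 1.046 for arsenate). The log2 ratio of a row is that of its scaled reads with 0.5 reads added to each library, and its 95% interval is the exact Clopper-Pearson interval of its share of the reads of the 2 libraries, without added reads. Rows with a mean of at least 20 reads over the 3 libraries were compared. A row was called when its log2 ratio was at least 1 in size and its interval excluded 0. The median interval width was 0.456 for arsenite against control, 0.393 for arsenate against control and 0.464 for arsenite against arsenate, on the log2 scale. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

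The comparisons and 22 gene lists were fixed at the same time as the alternatives below. Of the lists, 11 had at least 4 tested rows and received a median with its percentile among 10000 random lists of the same size drawn from 20 bins of mean reads, as a description of these libraries. Random lists draw rows singly, whereas list members can be neighbours read from the same transcript. A percentile can thus look more extreme than separate genes would give. The others give values per gene. 4 lists (ribosomal proteins, general stress and cold shock, mobile elements and prophage, fatty acid degradation) matched no symbol and gave 0 rows. Those for ribosomal proteins and for mobile elements had been defined by product names alone, so no symbol could match them. The genes named are all ars rows, the 8 rows with a symbol highest and the 8 lowest in each comparison with the control (5 and 5 for arsenite against arsenate) whose interval lay wholly beyond 2-fold, and up to 4 rows with the largest ratio per list. Locus tags were limited to 2 higher and 2 lower. Genes and stretches named outside this rule are said to have been chosen after their values were seen. Members of lists with fewer than 4 tested rows are given in full for the comparisons with the control only.

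The ratio, interval and call were tested on simulated counts for the real genes with 200 genes changed. Higher and lower changes were equal in number and size there, so the test cannot show scaling error from an unbalanced change. With Poisson counting error, 99.0%, 100% and 100% of genes changed 3-fold were called in the simulations of arsenite against control, arsenate against control and arsenite against arsenate, run on 4477, 4482 and 4485 genes, and 5 unchanged genes were called in each. Intervals held the true ratio in 95.4%, 94.8% and 95.4% of genes. With an assumed coefficient of variation of 0.2 between cultures, which these libraries cannot measure, 84%, 88.9% and 84.8% of 3-fold changes and 100% of 8-fold changes were called, 104, 117 and 104 unchanged genes were called, and the intervals held the truth in 40.9%, 40.5% and 41.6% of genes.

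The alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, total-count scaling, the authors' FPKM with a pseudocount of 1 or 0.1, no filter on low counts, a mean of at least 100 reads, an interval wholly beyond 2-fold, a log2 ratio of at least 2, 5 reads added, and rRNA rows kept. The Spearman correlation was the alternative for the shared response. Another 3 were added after seeing the data: the authors' own size factors, only rows with a locus of their own, and TMM without the noncoding RNA rows.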

Results

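RNA was sequenced from log-phase cells of Lysinibacillus sp. B2A1, a bacterium of a spore-forming genus, after 3 h with or without arsenic in the same defined medium. The 3 libraries were a control without arsenic, a library from cells exposed to 5 mM sodium arsenite, the As(III) form, and a library from cells exposed to 50 mM disodium hydrogen arsenate, the As(V) form. Each condition had 1 library, so no difference below has a replicate check, no p-value is given, and every comparison is between libraries. The libraries held 11022559 reads in genes for the control, 11081333 for arsenite and 10892999 for arsenate. The TMM scaling factors were 1.235, 0.774 and 1.046, so the effective depth differed more than these totals. Of the 5417 gene rows in the files, 4490 reached a mean of 20 reads over the 3 libraries and were compared, and 371 of these carried a gene symbol. A gene is called higher or lower when its scaled read ratio was at least 2-fold and the 95% counting interval of the ratio excluded 0 on the log2 scale. The intervals in square brackets cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. Coordinates are on the chromosome sequence that the files name, with the first base counted as 1, and no reference annotation was used here.

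The series asks how the transcriptome differs under each form of arsenic, and the first comparison set the arsenite library against the control. The 6 rows with ars symbols stood above every other row with a symbol. arsC, the arsenate reductase gene at 3213209 to 3213628, had a log2 ratio of 10.69 [10.19 to 11.31], from 28 reads in the control to 29746 with arsenite, or 1657-fold. Its neighbours arsB (3211819 to 3213196), for an arsenite efflux pump, arsA (3213991 to 3216038), for the ATPase that drives such a pump, and arsM (3216051 to 3216854), for an arsenite methyltransferase, had log2 ratios of 10.02 [9.64 to 10.47], 9.70 [9.48 to 9.95] and 9.83 [9.44 to 10.28]. Another arsM row at 3474684 to 3475499 and another arsB row at 3475500 to 3476564 reached 8.0 [7.72 to 8.30] and 7.78 [7.47 to 8.13]. Together the 6 rows took 0.00413% of the reads in the control (exact interval 0.00376% to 0.00453%) and 1.77% (1.77% to 1.78%) with arsenite. The median log2 ratio of this list was 9.77, above the medians of all 10000 random lists matched on expression. The first arsB and arsA rows each share a locus with an overlapping row, and how reads were divided between such rows, or between the 2 arsB and the 2 arsM rows, is not given in the sources used here.

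The map of the regions shows that the neighbours of these genes were higher too. A stretch of 11 neighbouring rows from 3209792 to 3218546 that holds arsB, arsC, arsA and arsM had a median log2 ratio of 9.90 with arsenite and 9.19 with arsenate, and 4 of these rows share a locus. Its highest row in both comparisons with the control, C3943_15300 at 3213630 to 3213989, lies between arsC and arsA and had log2 ratios of 11.03 [10.22 to 12.16] and 10.20 [9.39 to 11.33] on 10 control reads. The files do not pair locus tags with product names, so this row is given by its tag alone. A stretch of 5 rows from 3472405 to 3476882 with the other arsM and arsB had medians of 6.61 and 6.53. A stretch of 5 rows without symbols from 51655 to 56112 had medians of 6.05 with arsenite and 4.35 with arsenate. It held 7888 reads in the control, 575808 with arsenite and 222444 with arsenate. In both arsenic libraries this was more than the 6 named ars rows, which held 196446 reads with arsenite and 172506 with arsenate. These stretches, with at least 4 neighbouring rows at 8-fold or more, were defined after the values were seen, and neighbouring rows can be read from the same transcript.

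**Figure D1:**
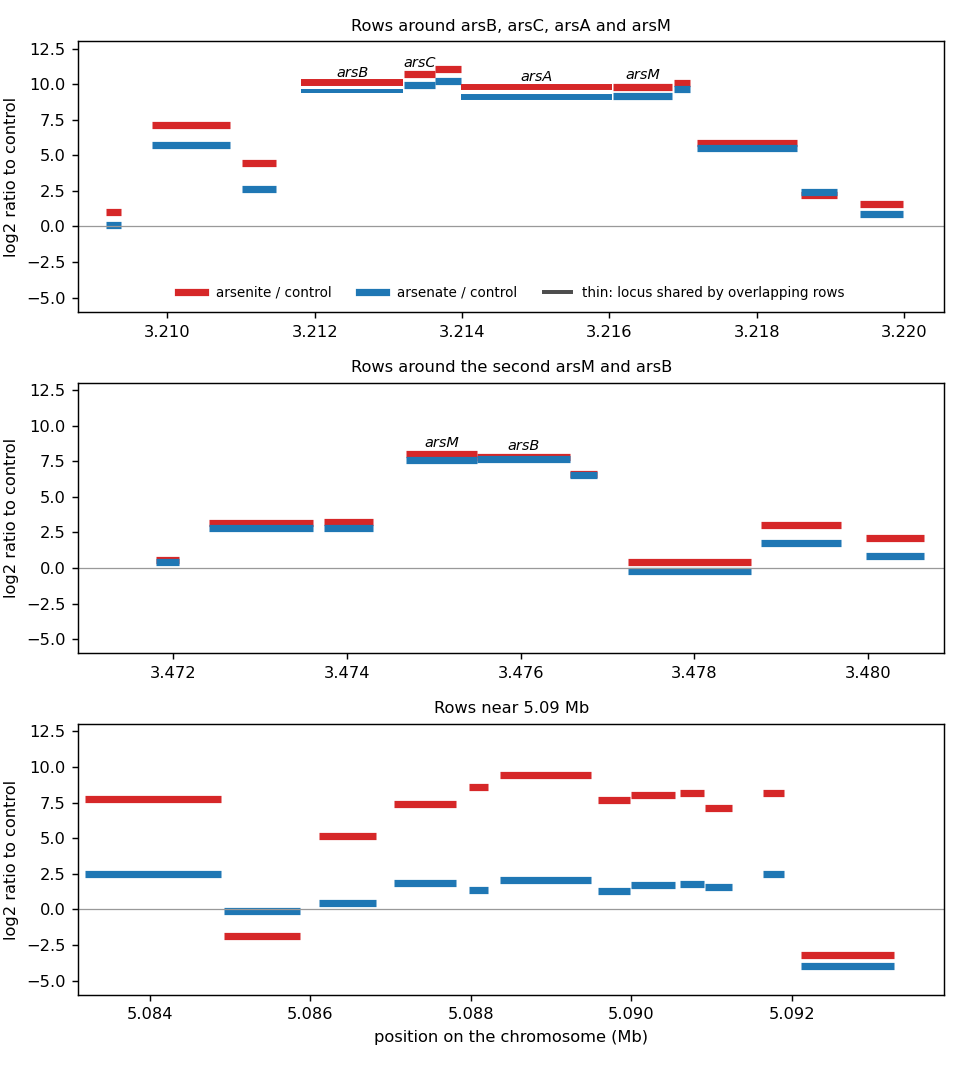
Log2 ratios to the control library (vertical axis) along the chromosome in Mb (horizontal axis) for tested gene rows around the 2 groups of ars genes and around a stretch of 9 rows without symbols. Each bar spans a locus, red for arsenite and blue for arsenate; both colours lie above 9 at arsB, arsC, arsA and arsM in the top panel and between 7.55 and 8.0 at arsM and arsB in the middle panel, whereas in the bottom panel the 9 rows have medians of 8.04 with arsenite and 1.73 with arsenate.

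Over all tested genes, 593 were higher and 799 lower with arsenite, and 48 were at least 16-fold higher and 26 at least 16-fold lower. Genes for protein quality control were among the higher ones: clpP, the proteolytic subunit of the Clp protease, had a log2 ratio of 2.02 [2.01 to 2.04] and the chaperonin gene groL 1.17 [1.16 to 1.19], while the protease gene lon had -0.70 [-0.79 to -0.61]. All 3 rows of the iron-sulfur cluster assembly list were higher, namely sufB at 1.55 [1.51 to 1.59], sufD at 1.99 [1.93 to 2.05] and sufC at 2.22 [2.15 to 2.29]. These suf rows lie between 4354623 and 4359876 and can be read from the same transcript. In the list for thiol and oxidative stress defence, 2 of 9 rows were higher, the thioredoxin gene trxA at 1.44 [1.40 to 1.48] and the methionine sulfoxide reductase gene msrB at 1.18 [1.10 to 1.25]. In the same list 1 row was lower, msrA at 3525411 to 3525932 at -1.27 [-1.46 to -1.09], while another msrA row was at 0.44 and not called. In the list for cysteine, methionine and sulfur assimilation 2 of 7 rows were higher and 3 lower, with a median of -0.80. sat and cysC, for ATP sulfurylase and adenylylsulfate kinase, overlap in a shared locus and were at 2.04 [1.81 to 2.27] and 1.72 [1.43 to 2.01]. The serine acetyltransferase gene cysE and the sulfonate utilization gene ssuE, by contrast, were at -2.24 [-2.88 to -1.69] and -2.24 [-2.66 to -1.87]. The list for metal efflux and metal sensing matched 4 rows, with the symbols nikA, corA and mgtE only. It thus held no known efflux pump or metal sensor gene. A nikA row at 3124765 to 3126324, for a nickel-binding protein, was higher at 2.5 [1.98 to 3.08]. Another nikA row at 3440641 to 3442224 was lower at -1.87 [-2.20 to -1.57], and corA and mgtE were not called.

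With arsenite 2 of 3 phosphate uptake rows, 8 of 17 amino acid synthesis rows and 3 of 10 flagellum rows were lower. pstC and pstA, for the permease of the phosphate ABC transporter, had log2 ratios of -3.08 [-3.98 to -2.36] and -1.76 [-2.20 to -1.36], and the regulatory gene phoU next to them had -0.41 [-0.79 to -0.04] and was not called. In the amino acid synthesis list (branched-chain, arginine, histidine and aromatic), 8 of 17 rows were lower and 1 higher, with a median of -0.70 at percentile 2.23 of the random lists. Its lowest rows were ilvB for acetolactate synthase at -2.62 [-3.27 to -2.07], hisA at -2.18 [-2.30 to -2.06], leuC for isopropylmalate isomerase at -2.13 [-2.62 to -1.70] and hisD at -2.08 [-2.71 to -1.53]. The trp symbols, looked at afterwards, did not share this fall. The 4 trp rows (trpB, trpB, trpD and trpS, which is not in this list) had a median of 0.90. The highest was called higher at 1.19, and only trpS was called lower. In the flagellum and chemotaxis list 3 of 10 rows were lower and none higher, with a median of -0.90 at percentile 1.1. These 3 were the rod gene flgC at -3.02 [-3.29 to -2.77], flgG at -1.73 [-1.92 to -1.54] and fliH at -1.11 [-1.23 to -1.0]. They lie between 1324285 and 1334423, and rows this close can be read from the same transcript. All 10 rows of this list carry flg, flh or fli symbols. It matched no che or mot symbol, so its values do not cover chemotaxis genes. The aminoacyl-tRNA synthetase genes trpS and cysS were at -1.61 [-1.99 to -1.27] and -1.21 [-1.44 to -1.0], and lysS was at -0.45. Of the sporulation list, sigF, for the forespore sigma factor, and spoIIAA, for a protein that controls it, were at -1.89 [-2.96 to -1.05] and -2.64 [-4.25 to -1.55], on 73 and 64 control reads, and spo0A was at 0.52. Of the spo rows outside the list, seen afterwards, spoVAE was higher at 1.83 [1.11 to 2.62] and spoIID lower at -1.23 [-2.05 to -0.53]. The heme uptake gene isdC was at -2.12 [-2.37 to -1.87] and isdE at -0.18.

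In the citrate cycle list 2 of 5 rows were higher, the fumarase gene fumC at 1.34 [1.22 to 1.46] and the malate dehydrogenase gene mdh at 2202969 to 2203907 at 1.11 [1.05 to 1.16]. In glycolysis and gluconeogenesis 1 of 9 rows was higher, pdhA of the pyruvate dehydrogenase complex at 2.09 [2.07 to 2.11]. In the ATP synthase and respiratory chain list 2 of 10 rows were lower, the quinol oxidase gene qoxA at -2.12 [-2.34 to -1.91] and ctaG at -1.64 [-1.74 to -1.54], and 1 qoxD row was higher at 1.24 [0.43 to 2.10] on 22 control reads. In the DNA repair list 2 of 8 rows were lower, mutY at -1.31 [-1.91 to -0.77] and ligA at -1.14 [-1.30 to -0.98], and recA was at 0.56. The osmoprotectant and sodium transport list matched 4 rows, with the symbols nhaC, putP and mscL only. Of these, an antiporter row nhaC at 508770 to 510215 was lower at -1.34 [-1.45 to -1.24]. The purine synthesis rows purH and purE were at -0.46 and -0.57. These counts stand beside 593 higher and 799 lower among all 4490 tested rows. List medians lay at percentile 28.8 for glycolysis, 32.7 for the respiratory chain, 37.2 for DNA repair and 56.5 for osmoprotectants and sodium. They lay at 58.0 for thiol defence, 60.6 for the citrate cycle and 71.0 for the metal list, against 4.22 for sulfur assimilation. Outside the lists, the highest symbols after the ars rows were ytxJ at 4.33 [3.69 to 5.12] and the ribosomal protein gene rpmG at 5111882 to 5112031 at 3.38 [2.71 to 4.19], each on 19 control reads. The lowest were the cell division gene zapA at -4.31 [-5.53 to -3.44], the phenylacetate degradation genes paaI at -3.25 [-4.84 to -2.19] and paaG at -3.08 [-4.17 to -2.26], dltA for D-alanylation of teichoic acids at -2.76 [-3.0 to -2.52] and the recombinase gene xerC at -2.74 [-2.96 to -2.54]. The lowest row of all, C3943_09585 at 2061015 to 2063154, had 19113 reads in the control and 88 with arsenite, a log2 ratio of -7.09 [-7.42 to -6.79], and shares its locus with another row.

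Stable noncoding RNAs took a larger share of the reads in both arsenic libraries. rnpB, ssrA, the 2 ssrS rows and ffs, for the RNAs of RNase P, trans-translation, 6S RNA and the signal recognition particle, held 4.47% of the control reads, 8.38% with arsenite and 9.27% with arsenate. These 5 rows, chosen after their values were seen, had log2 ratios of 1.22 to 2.47 with arsenite and 1.06 to 1.87 with arsenate. Scaling sets the balance of higher and lower genes: with total-count scaling each log2 ratio of arsenite to control shifted by -0.67, and 205 genes were higher and 1627 lower, so that higher genes made up 11.2% of the calls instead of 42.6%. Under that scaling groL, trxA, msrB, sufB, qoxD, fumC, mdh, rnpB, ssrA and 1 ssrS row were no longer 2-fold higher, and the medians of the thiol, metal, citrate cycle and glycolysis lists, 0.28, 0.24, 0.30 and 0.14, turned to -0.39, -0.44, -0.37 and -0.53. More rows were lower: 7 of 10 flagellum rows, 11 of 17 for amino acid synthesis with none higher and all 3 for phosphate. Among the genes named above, lon was lower at -1.37, phoU at -1.08, lysS at -1.13, mgtE at -1.07, purH at -1.13 and purE at -1.24. The mdh row at 2055526 to 2057112 was lower too, at -1.23.

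The next comparison set the arsenate library against the control. The ars rows were again the highest symbols: arsC had a log2 ratio of 9.91 [9.41 to 10.53], arsB 9.51 [9.12 to 9.95], arsM 9.19 [8.80 to 9.64] and arsA 9.03 [8.80 to 9.28], and the other arsB and arsM rows had 7.67 [7.37 to 8.02] and 7.55 [7.28 to 7.86]. The 6 rows took 1.58% of the reads (exact interval 1.58% to 1.59%), and the list median of 9.11 was above those of all 10000 random lists. After them came fumC at 2.53 [2.42 to 2.63], which was 5.76-fold higher, and rpoN at 1599082 to 1600419, for an alternative sigma factor, at 2.43 [2.09 to 2.81]. The lowest symbols were paaI at -3.12 [-4.36 to -2.21], paaH at -3.03 [-4.83 to -1.84], ssuE at -2.63 [-3.05 to -2.26], mce at -2.48 [-2.73 to -2.24], paaG at -2.34 [-3.04 to -1.75], the biotin synthesis gene bioA at -2.25 [-2.77 to -1.79], spoIIAA at -2.23 [-3.36 to -1.35] and the cobalamin synthesis gene cobS at -2.03 [-2.77 to -1.40]. paaI and paaH overlap in a shared locus, and bioA, spoIIAA and cobS also share theirs with other rows.

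Over all tested genes 381 were higher and 391 lower with arsenate, with 28 at least 16-fold higher and none at least 16-fold lower. C3943_24900 at 5092112 to 5093278 fell just short of 16-fold lower, at -3.99 [-4.02 to -3.97]. It held 202264 reads in the control and 10634 with arsenate. With total-count scaling it was at -4.23, past 16-fold. Among central metabolism genes, 2 of 5 citrate cycle rows were higher, fumC and an mdh row at 2055526 to 2057112 at 1.84 [1.26 to 2.49], and pdhA was at 1.57 [1.55 to 1.59] while the glyceraldehyde-3-phosphate dehydrogenase gene gap was at -1.62 [-1.65 to -1.60]. pdhA and gap were the only calls among the 9 glycolysis and gluconeogenesis rows. In the respiratory chain list 3 of 10 rows were lower, qoxA at -1.73 [-1.90 to -1.56], ctaG at -1.14 [-1.22 to -1.06] and qoxB at 2384754 to 2386697 at -1.06 [-1.20 to -0.92]. The sodium and proline symporter gene putP was the 1 higher row among 4 for osmoprotectants and sodium, at 1.96 [1.76 to 2.17]. sufC and sufD were higher at 1.31 [1.24 to 1.38] and 1.11 [1.05 to 1.17], and sufB was at 0.75 [0.71 to 0.79]. In the flagellum and chemotaxis list 2 of 10 rows were lower, fliH at -1.07 [-1.18 to -0.97] and fliQ at -1.05 [-1.25 to -0.86], with a median of -0.69 at percentile 0.55. The amino acid synthesis list had 2 of 17 rows lower, hisA at -1.59 [-1.68 to -1.50] and leuC at -1.11 [-1.42 to -0.81], with a median of -0.51 at percentile 0.76. The 4 trp rows, looked at afterwards, were at 0.22 to 0.77, and none was called. Of the 7 sulfur assimilation rows only ssuE was called. No row passed among 9 for thiol and oxidative stress defence, 4 in the metal list (nikA, corA and mgtE symbols) or 8 for DNA repair. trxA was at 0.71 [0.67 to 0.74].

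The phosphate genes pstC, pstA and phoU were at -0.45 [-0.78 to -0.12], 0.14 [-0.10 to 0.38] and 0.61 [0.33 to 0.89] with arsenate. clpP, groL and lon were at 0.49, 0.31 and -0.38, trpS, lysS and cysS at 0.67, 0.13 and -0.05, and purH and purE at 0.40 and -0.60. sigF was lower at -1.06 [-1.75 to -0.44] and spo0A was at -0.08. isdC was lower at -1.02 [-1.18 to -0.86], while isdE was at -0.71 and not called. With total-count scaling each log2 ratio of arsenate to control shifted by -0.24, which gave 263 higher and 601 lower genes, or 30.4% higher among the calls instead of 49.4%. sufD, rnpB and 1 ssrS row were then below 2-fold, and the glycolysis median turned from 0.12 to -0.12, while 5 of 10 flagellum rows and 7 of 17 for amino acid synthesis were lower.

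**Figure D2:**
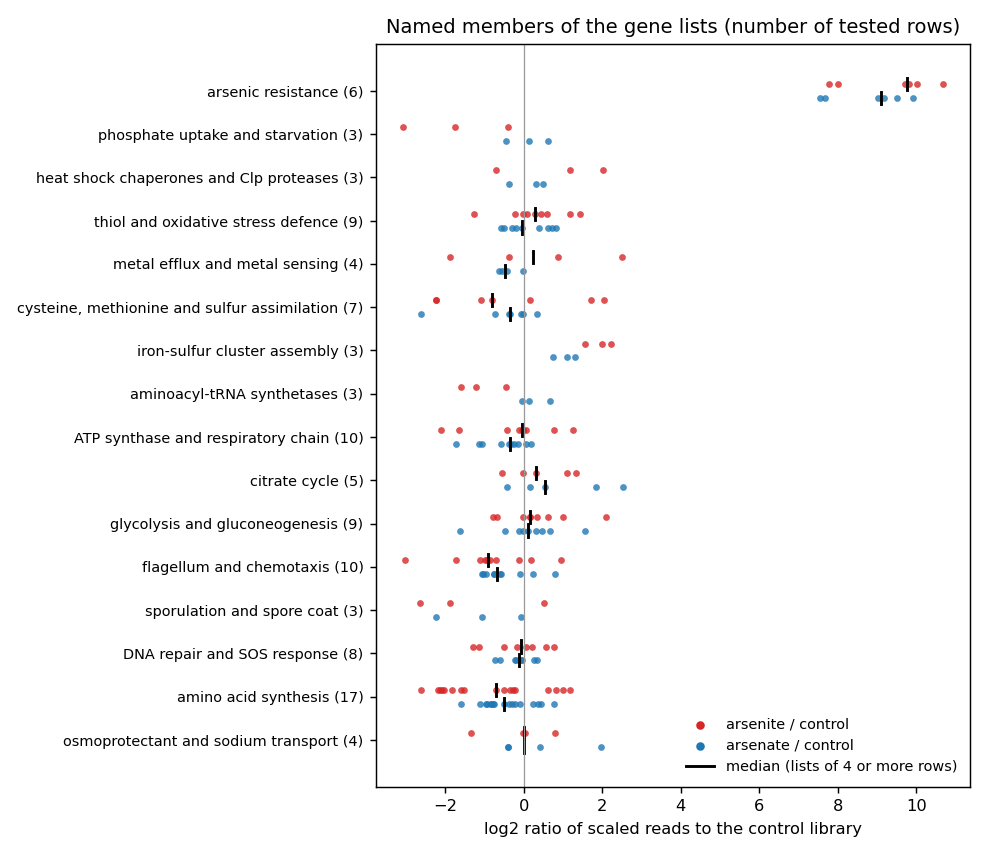
Log2 ratio to the control library (horizontal axis) of each tested row in the gene lists with at least 3 tested rows (vertical axis, number of rows in parentheses), red for arsenite and blue for arsenate, with a black tick at the median of lists of 4 or more rows. The 6 ars rows lie between 7.55 and 10.69, and the amino acid synthesis medians lie at -0.70 with arsenite and -0.51 with arsenate.

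The arsenite and arsenate libraries were then compared directly. The oxyanions differ in the oxidation state of arsenic, and the doses differed as well, 5 mM against 50 mM, so a difference cannot be given to the form of arsenic alone. None of the 6 ars rows differed by 2-fold: their log2 ratios of arsenite to arsenate ran from 0.11 [0.07 to 0.14] for the arsB row at 3475500 to 0.78 [0.76 to 0.81] for arsC, with a median of 0.58, and with total-count scaling they ran from -0.33 to 0.35. Far larger was the ratio of a stretch of 9 neighbouring rows without symbols at 5086112 to 5091904, whose median was 6.31. It held 314 reads in the control, 41873 with arsenite and 763 with arsenate, and its highest row, C3943_24870 at 5088372 to 5089499, had a log2 ratio of 7.39 [7.09 to 7.74]. The highest symbols were ytxJ at 4.08 [3.44 to 4.87], nikA at 3124765 to 3126324 at 3.04 [2.40 to 3.81], rpmG at 5111882 to 5112031 at 2.73 [2.13 to 3.44], the thiamine synthesis gene thiD at 662711 to 663541 at 2.32 [2.26 to 2.39] and cysC at 1.78 [1.48 to 2.10]. Lowest were zapA at -2.93 [-4.18 to -2.02], pstC at -2.63 [-3.55 to -1.90], mdh at 2055526 to 2057112 at -2.40 [-3.41 to -1.60], trpS at -2.29 [-2.66 to -1.95] and flgC at -2.26 [-2.54 to -1.99].

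In all 256 genes were higher and 509 lower with arsenite than with arsenate. All 3 phosphate rows were lower with arsenite, pstA at -1.90 [-2.34 to -1.49] and phoU at -1.02 [-1.39 to -0.66] beside pstC. clpP was higher at 1.54 [1.52 to 1.55], with groL at 0.87 and lon at -0.32, and the suf rows were at 0.80 to 0.91. Of 7 sulfur assimilation rows 2 were higher, sat at 1.69 [1.47 to 1.92] and cysC, which overlap in a shared locus. cysE was lower at -1.85 [-2.51 to -1.27]. The amino acid synthesis list had 6 of 17 rows lower and none higher, led by ilvB at -1.83 [-2.50 to -1.24], ilvD at -1.49 [-1.74 to -1.25] and leuB at -1.19 [-1.94 to -0.53], with a median of -0.41 at percentile 8.61. The flagellum list had 2 of 10 lower, flgC and flgG at -1.63 [-1.83 to -1.44], and a median of -0.08. fumC was lower at -1.19 [-1.27 to -1.10], as was 1 other of 5 citrate cycle rows, the mdh row named above. putP was lower at -1.17 [-1.37 to -0.97], and so were cysS at -1.16 [-1.39 to -0.94], isdC at -1.10 [-1.37 to -0.83] and nikA at 3440641 to 3442224 at -1.24 [-1.58 to -0.91]. In the respiratory list 1 of 10 rows was higher, the qoxD row at 3499439 to 3499723 at 1.19 [0.35 to 2.10] on 33 and 19 reads. No row passed among 9 for thiol defence, 9 for glycolysis, 8 for DNA repair or 3 for sporulation, and purH and purE were at -0.86 and 0.03. The thiol list was matched by symbol and does not hold ytxJ, the highest symbol here, so its count does not cover that gene. With total-count scaling each log2 ratio shifted by -0.44, and 97 genes were higher and 1035 lower, or 8.57% higher among the calls instead of 33.5%. The qoxD row was then below 2-fold, 8 of 17 amino acid synthesis rows were lower, and lysS, purH, sigF, mutY, the msrA row at 3525411 and the nhaC row at 508770 were lower too.

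The last comparison asked how far the responses to the 2 forms ran together, as in the plot of both ratios. Across the 4490 genes, which are not independent replicates, the log2 ratios of arsenite and of arsenate to the control had a Pearson correlation of 0.758, a Spearman correlation of 0.702 and a covariance of 0.984. Leaving out the 6 ars rows gave a correlation of 0.738 and a covariance of 0.874. Both ratios use the same control library: unchanged libraries simulated with counting error alone gave a correlation of 0.421 and a covariance of 0.0142, and with an assumed coefficient of variation of 0.2 between cultures 0.486 and 0.0999. In both arsenic libraries 208 genes were higher, against 50.3 for independent lists of these sizes, and 309 were lower, against 69.6. The simulated unchanged libraries, which share the control, gave overlaps of 0.44 higher and 0.13 lower genes with counting error alone. With the assumed variation the overlaps were 14.04 and 6.13, against 0.83 and 0.87 for independent lists. The simulated lists were far shorter than the observed ones. With the assumed variation they held 61.65 and 60.08 higher genes for arsenite and arsenate, and 64.86 and 60.35 lower. Their overlaps therefore cannot be set directly beside 208 and 309. With 1 control library the control could not be split, so how much of the excess comes from it cannot be told. 7 genes were called in opposite directions.

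**Figure D3:**
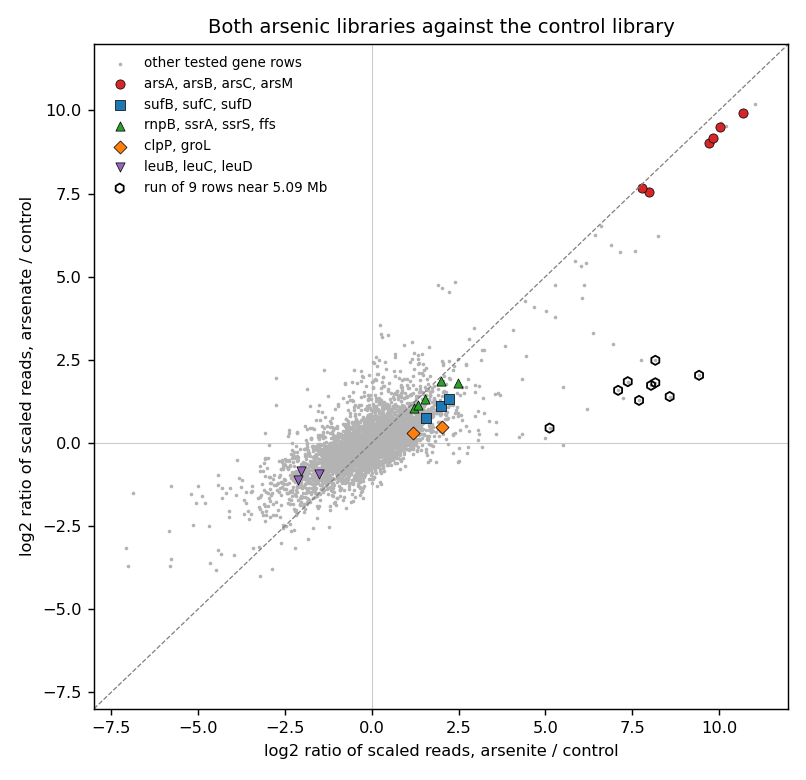
Log2 ratio of scaled reads of arsenate to control (vertical axis) against that of arsenite to control (horizontal axis) for the 4490 tested gene rows, with the line of equal ratios dashed. The 6 ars rows lie near the dashed line between 7.55 and 10.69, and the open hexagons, 9 neighbouring rows without symbols, lie far below it.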

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

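C3943_23940, at 4891942 to 4892973 on the chromosome, stood out because the 2 arsenic libraries lay on opposite sides of the control: its log2 ratio was -2.75 [-2.83 to -2.67] with arsenite and 1.96 [1.94 to 1.99] with arsenate. It held 15814 reads in the control, 1479 with arsenite and 51642 with arsenate, and its log2 ratio of arsenite to arsenate was -4.71 [-4.79 to -4.64]. With 1 library per group the difference was not tested against the spread between cultures. It is 1 of 7 genes called in opposite directions, all lower with arsenite and higher with arsenate.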

How the results depend on the processing

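No paired analysis was possible because each group has 1 library. Some list medians near 0 changed sign, most of them with total-count scaling or with only the rows that have a locus of their own. Total-count scaling gave 205 higher and 1627 lower genes for arsenite against control, 601 lower for arsenate against control, and 97 higher and 1035 lower for arsenite against arsenate, with 103 genes higher and 548 lower in both arsenic libraries. This follows from its construction, which lowers every ratio in a comparison by the same amount. A log2 ratio of at least 2 gave 142 higher and 246 lower for arsenite against control, 94 and 50 for arsenate against control, and 51 and 100 for arsenite against arsenate, with 52 higher and 44 lower in both. Intervals wholly beyond 2-fold gave 251 higher and 237 lower for arsenate against control, 149 and 267 for arsenite against arsenate, and 195 lower in both. Both of these are stricter by construction. The Spearman correlation of the shared response was 0.702 against a Pearson correlation of 0.758, and the cause was not tested. The other 95 checks of these counts and correlations stayed within 1.5 times the main count, or within 0.05 for a correlation. Not all of them could have failed. Scaling by 1 factor per library cannot change a correlation. DESeq2 factors shifted the log2 ratios of a comparison by only -0.0141 to 0.0067, so little could move. The tallies of unmoved checks here and below thus say less than their size. DESeq2 factors gave 587 higher and 805 lower for arsenite against control, and the authors' size factors, chosen after seeing the data, 577 and 817. Of the list medians 79 moved beyond their interval and 302 did not, 35 of the 79 with total-count scaling. Of the named gene values 284 moved and 1535 did not, 200 of the 284 with total-count scaling. Depth limits the rows with few reads: zapA rests on 9 reads with arsenite and paaI on 6, and their intervals span over 2 log2 units.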

Other observations

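The families below, the stretches of neighbouring rows and the test of the control standing apart with all its block lengths were chosen after the results were seen. Among 40 families of at least 3 tested rows whose symbols share their first 3 letters, several lay wholly or mostly on 1 side. Members of a family can be neighbours read from the same transcript, as paaG, paaH and paaI or leuC and leuD may be. Such members are not separate observations. The nucleoside catabolism genes deoB, deoC and deoD were all higher with arsenite, with log2 ratios of 1.51 to 1.99, and 2 of the 3 stayed called with total-count scaling, while with arsenate deoC alone was called and the ratios were 0.66 to 1.16, and with total-count scaling that call was lost. The phenylacetate genes paaG, paaH and paaI were lower in both arsenic libraries and the repressor gene paaX was called in neither, at -0.10 and 0.13. Of 5 rows for pseudaminic acid synthesis (pseB, pseH, pseG, pseI, pseC), 3 were lower with arsenite and 4 with arsenate, with medians of -1.01 and -1.18, and all 5 in both with total-count scaling. dltA and dltB were lower with arsenite and dltD, at -0.83, only with total-count scaling. leuB, leuC and leuD were all lower with arsenite, at -2.13 to -1.51, and with arsenate leuC was called, or all 3 with total-count scaling. Of 5 fatty acid synthesis rows (fabZ, fabF and fabD symbols) 4 were higher with arsenite than with arsenate, with a median of 1.11, but with total-count scaling none was called and the 5 ratios ran from -0.53 to 0.71. Of 8 cobalamin synthesis rows, 4 were lower with arsenite and 2 with arsenate, or 6 and 3 with total-count scaling. The 6 spo rows went both ways: with arsenite 1 was higher and 2 lower, with a median of 0.27, and with arsenate 1 was higher and 1 lower, with a median of -0.07.

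Ribosomal protein genes with a symbol, 8 rows also chosen after, had a median log2 ratio of 0.31 with arsenite and 0.28 with arsenate. With arsenite 2 rpmG rows were higher, at 3.38 and 1.81, and rplV was lower at -2.17 [-2.31 to -2.02]. With arsenate rplV alone was called, at -1.33 [-1.43 to -1.23]. With total-count scaling the arsenite median was -0.37 and the arsenate median 0.04. Stretches of at least 4 neighbouring rows at 8-fold or more below the control were seen with arsenite at 597551 to 602936, 707236 to 712606 and 3142251 to 3145666, with medians of -4.39, -4.32 and -5.11. Their medians with arsenate were -1.29, -1.26 and -3.42.

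The noncoding RNA rows rnpB, ssrA, ssrS and ffs were higher in both arsenic libraries. A general shift towards short features would raise other short rows too, but 575 other rows under 400 bases exceeded longer rows by a median log2 of 0.34 with arsenite and 0.16 with arsenate, less than the lowest noncoding row. With total-count scaling all stayed above the control, the lowest at 0.54, which restates their larger share of the reads, and rnpB, ssrA and 1 ssrS row were then under 2-fold with arsenite. A change in the amount of messenger RNA against stable RNA under arsenic may be behind this, as a hypothesis, and RNA extraction or fragment selection that differed between the libraries stays open beyond the test of short rows.

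The arsenite and arsenate ratios to the control correlated across genes. Counting error of the shared control is too small for this, since its simulated covariance was 1.44% of the observed value. If the control library stood apart and the arsenic libraries were unrelated, the covariance of the ratio of arsenite to arsenate with that of arsenate to control should lie below 0 by at least the variance of the arsenate library, of which counting error alone is 0.0158. Over all tested rows it was 0.0578. The lower bound was 0.0232 when single rows were resampled and -0.00988 to 0.00514 for blocks of 5, 10, 20, 50 and 100 neighbouring rows. Without the named ars rows, whose unnamed neighbours stay in, the block bounds were -0.0130 to -0.00059. None of these bounds reaches -0.0158, which argues against this as the whole cause only when the most extreme rows are counted. With arsenate just 39 rows were at least 8-fold higher and 15 at least 8-fold lower. The rows with an arsenate ratio under 8-fold are thus nearly all of the tested rows. For them the covariance was 0.0343, with bounds of 0.0081 for single rows and -0.0198 to -0.00612 for blocks. Of these 5 block intervals 2, those of 50 and 100 rows, reach past -0.0158. This cut uses the arsenate ratio, which enters the covariance, so -0.0158 is not an exact limit for these rows. With 1 control library a control that stood apart and a response common to both forms of arsenic cannot be told apart for them.

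The stretch at 5086112 to 5091904 was far higher with arsenite than with arsenate, with a median log2 ratio of 6.31 over 9 rows. None of its rows shares a locus with another (0% of rows, for splitting of reads between overlapping rows). The uniform shift of total-count scaling takes the median to 5.88. Its median against the control was 8.04 with arsenite and 1.73 with arsenate. It may be a set of genes that responds more to 5 mM arsenite than to 50 mM arsenate, a hypothesis that a replicate culture could test. A difference between these 2 cultures that does not come from arsenic was not tested and stays open.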
